A study of Mus musculus with 6 samples.

How the data were processed

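RNA was measured in hindlimb skeletal muscle of wild-type mice on a mixed strain background at postnatal days 2, 7 and 14, in 2 libraries per stage. Per the labels' protocols, RNA was taken with Trizol and libraries were built from 200 ng of total RNA with a stranded kit and ribosomal depletion; whether the counting used the strand is not given. The authors used CASAVA 1.2-14, FastQC 0.10.1, TopHat2 2.0.8, Cufflinks 2.2.1 and Cuffdiff 2.2.1 on GRCm38, per the submitters' processing notes, which give no annotation, settings or order of steps. The deposited FPKM values, 1 column per library, cover 39010 genes, of which 9514 are listed at 0 in all libraries, and any scaling between libraries is not stated. The authors also deposited comparison tables between stages and between the 2 libraries of a stage, which hold, per the file headers, a ratio as fold change and a p-value that is not adjusted. Read from the values, that ratio is the larger FPKM over the smaller with values below 1 raised to 1. Of the gene identifiers 37449 (96.0%) are in GENCODE M21, and 19 identifiers stand on more than 1 line of the table.

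The values were analysed here as log2(FPKM + 1) for genes with an FPKM of at least 1 in at least 2 of the 6 libraries, which left 13566 genes, 12048 of them protein-coding. A linear model with a mean per stage was fitted to all 6 libraries in 1 fit with limma 3.58.1 in R 4.3.3, with a variance trend and empirical Bayes moderation (3 residual and 3.80 prior degrees of freedom). Stages were compared in pairs, and with an F test over the 3 stages. The p-values were two-sided and adjusted by Benjamini-Hochberg over all tested genes, and a gene was called at an adjusted p below 0.05. A peak at P7 is a gene called higher at P7 than at P2 and lower at P14 than at P7, and a trough is the opposite. Fold changes are log2 differences of stage means with the SE of the fit, and FPKM is given as mean ± SD of 2 libraries. No fold is given against a stage listed at 0. The median SE of a log2 difference was 0.19.

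Lists of genes were written before the values were seen, with 804 members of which 795 matched a gene; members without a match are not analysed here. The lists covered myogenic regulators, myoblast fusion, cell migration and chemotaxis, growth signalling, developmental muscle isoforms, adult fast fibre genes, slow fibre genes, excitation-contraction coupling, neuromuscular junction, cell cycle, replication-dependent histones, extracellular matrix, oxidative phosphorylation, glycolysis and glycogen, fatty acid oxidation, ribosomal proteins, imprinted growth network, circadian clock, immediate early and stress genes, and markers of satellite cells, fibroblasts and fibro-adipogenic cells, endothelium, mural cells, macrophages, neutrophils and marrow, lymphocytes, erythroid cells, Schwann cells, adipocytes, cartilage and bone, tendon and skin. Marker lists describe bulk tissue and name no cells. The 30 lists with at least 5 tested members were tested with camera against all other genes with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with a correlation estimated from the residuals. The second test also refers its statistic to the 3 residual degrees of freedom, so it could call few lists. For P7 versus P2 the developmental isoforms, at an estimated correlation of -0.015, went from an unadjusted camera p of 3.44e-06 to 0.0161. A call lost under it therefore does not show that correlation between genes made the call. Sex-linked transcripts and mitochondrially encoded mRNAs were read as values only.

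Genes named in the text follow a rule written before the values were seen. In each comparison it takes the 6 protein-coding genes with the largest rise and the 6 with the largest fall among called genes with a mean of at least 5 FPKM and libraries of both stages fully separated, up to 3 members of each list with the largest absolute fold change whether called or not, and up to 5 protein-coding peak and trough genes. It always takes Tmem8c, Myod1, Myog, Pax7, Myh3, Myh8, Myh1, Myh2, Myh4, Igf1, Igf2 and Mstn. The text gives all of these for P14 versus P2 but only some for P7 versus P2 and P14 versus P7. Lists that were not called are likewise described for P14 versus P2 only. Absence from the text of the other comparisons is therefore not a result.

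Alternatives fixed beforehand were a pseudocount of 0.1 or 5, no filter or an FPKM of at least 5, median-of-ratios scaling, quantile normalization, scaling to the sum of protein-coding genes, protein-coding genes only, no variance trend, robust moderation, a replicate block, only the 4 libraries compared, each library left out in turn, an estimated correlation, the rotation test fry, and a log2 change of at least 1. A sex term and an adjustment of the authors' p-values were added after the data were seen. The analysis was tested on simulated data drawn from the means and spread of the real 13566 genes with 200 changed genes. It recovered 45% of changes of 1 on the log2 scale and 98% of changes of 2 with 6 false calls for P7 versus P2, 51% and 98% with 14 for P14 versus P7, and 49% and 97% with 9 for P14 versus P2. These data were independent normal values for each gene, with no floor at 0 and no shift shared by the genes of a library. The false calls are therefore not an error rate for the real libraries. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 made the other tables and the figures.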

Results

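Gene expression was measured by RNA sequencing in hindlimb skeletal muscle of wild-type mice on a mixed strain background at postnatal days 2, 7 and 14 (P2, P7 and P14). There were 2 libraries per stage and 6 in all. The libraries were made from total RNA after ribosomal depletion, and expression is given as FPKM, a fragment count scaled for transcript length and library size. The design text calls the replicates biological, and whether they are separate animals is not stated, so the p-values measure only the spread between these samples. The sex-linked values below show that the libraries of P2, and those of P7, came from different animals, while for P14 this stays open. Between 12175 and 13337 genes per library had an FPKM of at least 1. Log2 values of the 2 libraries of a stage correlated across the 13566 tested genes at 0.952 for P2, 0.964 for P7 and 0.967 for P14, where genes are not independent replicates. The absolute depth is unknown. Depth relative to P2 replicate 1, read from the FPKM that 1 fragment was worth, was 96.4% for P2 replicate 2, 94.9% and 83.8% for the P7 libraries and 72.7% and 74.9% for the P14 libraries. These are medians over 114 gene lengths and hold if each library was scaled by its own total. Xist was at 74.7 FPKM in P2 replicate 2 and 61.2 in P7 replicate 1 and below 1 in the other libraries, which expressed the Y-linked gene Ddx3y at 13.5 to 28.4. Neither P14 library expressed Xist, so sex was not balanced between P14 and the other stages. Comparisons with P14 are therefore partly confounded with sex.

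Myosin heavy chain genes of the developing fibre gave way to those of adult fast fibres. Perinatal Myh8 (chromosome 11, 67277123 to 67308634 on GRCm38) fell from 1142 ± 112 FPKM at P2 to 30.8 ± 3.08 at P14 (SD, n = 2 per stage; log2 fold change -5.17 ± 0.21 SE, limma adjusted p = 0.000355). Embryonic Myh3 fell from 88.8 ± 14.3 to 4.86 ± 2.33. Myh4, the myosin of type IIb fibres, rose from 130 ± 167 to 2601 ± 565 (log2 fold change 5.52 ± 1.19 SE, limma adjusted p = 0.0194). Myh1 rose from 61.6 ± 55.5 to 621 ± 2.14 and Myh2 from 25.6 ± 14.2 to 256 ± 63.6. The log2 fold change of Myh1 was 2.61 without P2 replicate 1 and 4.73 without P2 replicate 2. The spread of Myh4 at P2 came from 11.7 FPKM in replicate 1 and 248 in replicate 2, and the log2 fold change was 3.37 without P2 replicate 1 and 7.66 without P2 replicate 2. The adjusted p of Myh4 was 0.0895 without P14 replicate 1 and 0.0608 without P14 replicate 2. The myosin genes of this cluster are similar in sequence, and how the authors shared fragments between such copies is not stated.

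**Figure D1:**
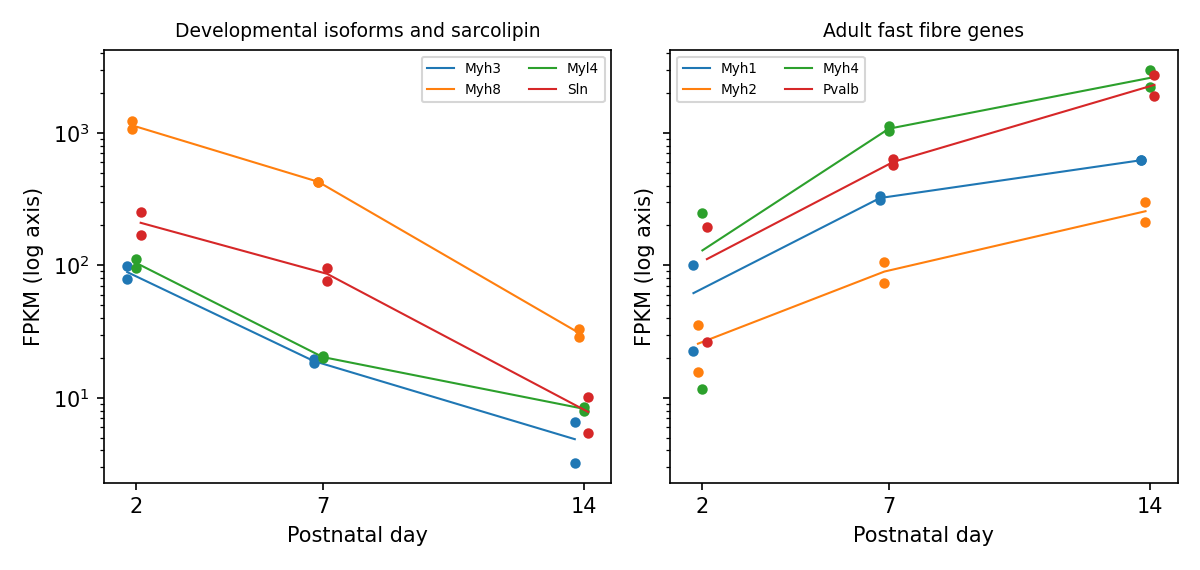
FPKM on a log axis against postnatal day, with points for the 6 libraries and lines through the stage means, for developmental isoforms and sarcolipin on the left and adult fast fibre genes on the right. Myh8 went from a mean of 1142 at P2 to 30.8 at P14 while Myh4 went from 130 to 2601, and the P2 points of Myh4 lie at 11.7 and 248.

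Of 23 tested adult fast fibre genes, 20 were higher at P14 than at P2 and none lower, and 21 were higher when adjusted over the list alone. Pvalb, a calcium buffer of fast fibres, rose from 111 ± 120 to 2303 ± 595 FPKM. The list median was 1.71 on the log2 scale against -0.05 over all genes, and the adjusted p of camera was 2.77e-11, or 0.409 with an estimated correlation. Of 13 developmental muscle isoforms, 8 were lower and 1 higher (9 and 1 adjusted over the list alone; camera adjusted p = 7.00e-05, and adjusted p = 0.409 with an estimated correlation). Myl4, an embryonic myosin light chain, fell from 104 ± 11.3 to 8.25 ± 0.464. The 30 genes of excitation-contraction coupling held 25 that were higher and 1 that was lower (27 and 1 adjusted over the list alone; camera adjusted p = 7.87e-13, and adjusted p = 0.409 with an estimated correlation). Kcna7, a potassium channel gene, rose from 1.58 ± 0.694 to 12.4 ± 2.47, and the lower gene was Ryr3, a ryanodine receptor gene, from 12.1 ± 1.62 to 1.79 ± 0.202.

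Genes of energy metabolism were mostly higher at P14 than at P2. In oxidative phosphorylation 51 of 55 tested genes were higher and none lower (55 higher adjusted over the list alone). Cox7a1 rose from 86.2 ± 51.4 to 449 ± 71.9 FPKM and Cox5a from 53.6 ± 21.4 to 173 ± 19.5. Without P14 replicate 1 their adjusted p was 0.0524 and 0.0588. In glycolysis and glycogen metabolism 27 of 33 were higher and 2 lower (28 and 3 adjusted over the list alone). Phka1, a phosphorylase kinase subunit, rose from 7.65 ± 1.26 to 53.0 ± 17.2. In fatty acid oxidation 17 of 28 were higher and none lower (21 higher adjusted over the list alone). Pdk4 rose from 14.3 ± 2.69 to 89.7 ± 9.45 and Ucp3 from 4.61 ± 2.08 to 24.3 ± 6.13. The camera adjusted p was 7.30e-20, 2.53e-10 and 2.36e-10 for these 3 lists, and adjusted p = 0.409 with an estimated correlation for each. With all 6 libraries, the largest rises among protein-coding genes were those of Myh4, Pvalb and Mb, myoglobin, which went from 12.5 ± 10.6 to 187 ± 7.24. Next came Ankrd23 (from 13.5 ± 8.32 to 211 ± 58.4), Klhl33 (from 0.679 ± 0.302 to 22.9 ± 3.30) and Tuba8 (from 1.80 ± 1.55 to 33.1 ± 7.98). The order depended on the P2 libraries. Without P2 replicate 1 the log2 change of Klhl33, 3.65, exceeded that of Pvalb, 3.52, and Myh4, 3.37. Without P2 replicate 2 Pvalb was at 6.37, against 4.94 with all libraries. The P2 libraries lay apart in these genes. Replicate 2 minus replicate 1 had a median of 0.68 on the log2 scale for adult fast fibre genes and 0.66 for oxidative phosphorylation against 0.25 over all genes.

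Genes of proliferation fell. Of 45 tested cell cycle genes 43 were lower at P14 than at P2 and none higher (44 lower adjusted over the list alone). Mki67 fell from 30.4 ± 4.73 to 6.01 ± 1.32 FPKM and Rrm2, a ribonucleotide reductase subunit, from 11.5 ± 0.178 to 2.00 ± 0.209. Of 47 replication-dependent histone genes 43 were lower and none higher (45 lower adjusted over the list alone), and these genes have near-identical copies, so the value of any member is uncertain. The camera adjusted p was 1.42e-20 for cell cycle and 1.60e-20 for histones, and adjusted p = 0.409 with an estimated correlation for both. The imprinted growth network held 12 lower and no higher genes among 18 (14 lower adjusted over the list alone; camera adjusted p = 1.93e-08, and adjusted p = 0.409 with an estimated correlation). Dlk1 fell from 196 ± 31.1 to 20.8 ± 1.43, Peg10 from 26.5 ± 2.60 to 2.30 ± 0.369 and Plagl1 from 121 ± 2.38 to 18.9 ± 1.02. Among genes named in advance, Igf2 fell from 515 ± 98.5 to 170 ± 9.52 (limma adjusted p = 0.00628). Igf1 fell from 42.1 ± 1.45 to 26.5 ± 1.11 (limma adjusted p = 0.0390). Its call was lost whichever library was left out, at adjusted p from 0.0642 without P2 replicate 1 to 0.161 without P14 replicate 2. Mstn, which encodes myostatin, was at 17.3 ± 4.13 and 21.8 ± 3.06 and did not pass the test. The growth signalling list as a whole was not called, with 4 higher and 5 lower genes among 38, the same when adjusted over the list alone. Trim63, a ubiquitin ligase of muscle, rose from 7.87 ± 0.543 to 38.3 ± 4.12 and Igfbp2 fell from 7.49 ± 1.01 to 0.638 ± 0.188.

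**Figure D2:**
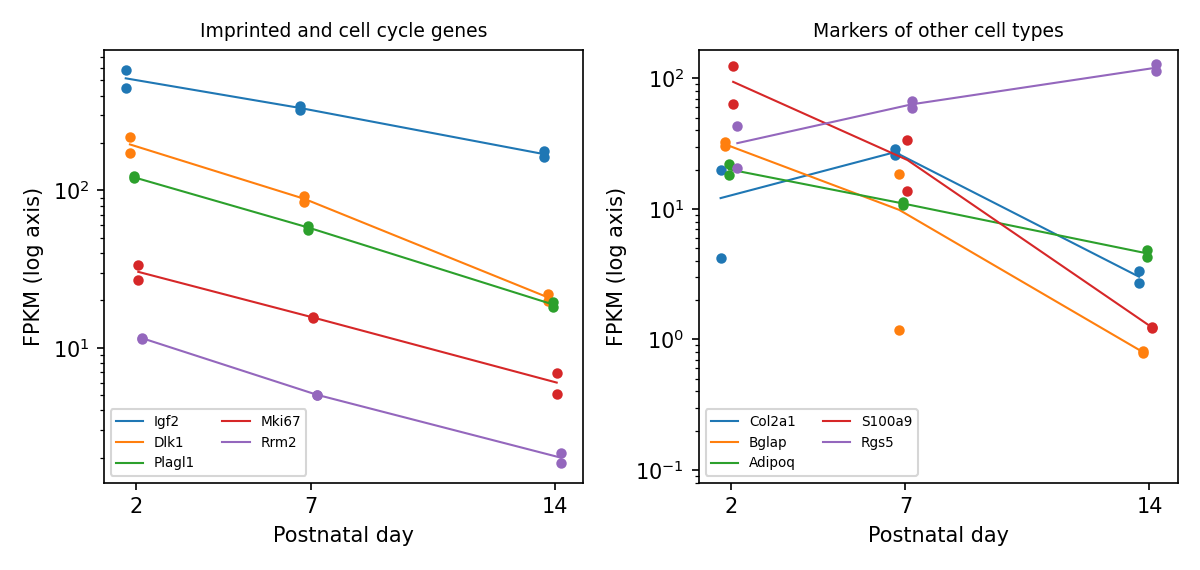
FPKM on a log axis against postnatal day, with points for the 6 libraries and lines through the stage means, for imprinted and cell cycle genes on the left and markers of other cell types on the right. Dlk1 went from a mean of 196 at P2 to 20.8 at P14, S100a9 from 94.1 to 1.24, and Bglap was at 18.5 and 1.18 in the 2 P7 libraries.

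Of the genes named for myoblast fusion, 9 of 38 were lower at P14 than at P2 and 1 higher (11 and 1 adjusted over the list alone; camera adjusted p = 0.00730, and adjusted p = 0.739 with an estimated correlation). Tmem8c, which encodes the fusion protein myomaker, fell from 9.64 ± 0.188 to 4.62 ± 0.795 FPKM (limma adjusted p = 0.00987, and 0.0579 without P14 replicate 2). Adam12 fell from 8.34 ± 2.12 to 2.13 ± 0.166 and Cdh2, N-cadherin, from 5.89 ± 1.36 to 1.61 ± 0.0436. The member that rose was Tmem182, from 28.8 ± 4.32 to 68.8 ± 8.88 (adjusted p = 0.0574 without P14 replicate 1). In cell migration and chemotaxis 12 of 43 genes were lower and 3 higher (14 and 3 adjusted over the list alone; camera adjusted p = 0.0308, and adjusted p = 0.804 with an estimated correlation). The camera adjusted p of cell migration and chemotaxis was 0.126 without P2 replicate 2. Mmp9, a gelatinase that neutrophils also express, fell from 13.6 ± 9.27 to 0.412 ± 0.0278, and Ncam1 from 18.4 ± 0.257 to 5.22 ± 0.447. In the extracellular matrix list 14 of 45 were lower and none higher, the same when adjusted over the list alone (camera adjusted p = 0.00140, and adjusted p = 0.804 with an estimated correlation). That of the extracellular matrix list was 0.0807 without P2 replicate 2. Postn, periostin, fell from 458 ± 40.1 to 111 ± 6.48 and Fbn2, fibrillin-2, from 21.6 ± 3.19 to 2.47 ± 0.428.

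Myogenic regulators were not called as a list at P14 versus P2, with 2 higher and 3 lower among 20 genes (4 and 6 adjusted over the list alone). Myod1 was at 6.08 ± 0.333 and 8.42 ± 2.29 FPKM and Myog at 29.7 ± 5.69 and 20.01 ± 3.13, and neither passed the test. Pax7, the satellite cell transcription factor, fell from 2.54 ± 0.315 to 1.39 ± 0.153 (limma adjusted p = 0.0405). This call too was lost whichever library was left out, at adjusted p from 0.0506 without P2 replicate 1 to 0.197 without P14 replicate 1. Slow fibre genes were also not called, with 1 higher and 4 lower among 16, the same when adjusted over the list alone, but were called lower without P14 replicate 2 (camera adjusted p = 0.00363). The P14 libraries lay apart in slow fibre genes, with replicate 2 minus replicate 1 at a median of 0.746 on the log2 scale against -0.125 over all genes. Sln, which encodes the calcium pump regulator sarcolipin, fell from 209 ± 58.7 to 7.81 ± 3.35. At the neuromuscular junction, a list not called, 2 of 19 genes were higher and 4 lower, the same when adjusted over the list alone. Chrne, the adult acetylcholine receptor subunit, rose from 1.41 ± 1.08 to 8.90 ± 2.99 (adjusted p = 0.0569 without P14 replicate 1). Chrng, the fetal subunit, fell from 3.34 ± 0.946 to 0.375 ± 0.200. Ribosomal proteins were not called, with 3 lower among 63 (1 adjusted over the list alone), and their processed pseudogenes make single values uncertain. Circadian clock genes were called higher, with 6 of 17 higher and none lower (11 higher adjusted over the list alone; camera adjusted p = 0.000102, and adjusted p = 0.409 with an estimated correlation). Nr1d2 rose from 8.89 ± 2.52 to 25.1 ± 1.62. Immediate early and stress genes held 4 higher among 17, the same when adjusted over the list alone (camera adjusted p = 0.0301, and adjusted p = 0.409 with an estimated correlation). The call of the immediate early and stress list was lost without P2 replicate 2 (0.140) and without P14 replicate 2 (0.208). Nr4a1 rose from 2.44 ± 0.0645 to 16.0 ± 3.27. The hour of sampling is not stated in the sources used here.

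Markers of other cell types moved in both directions from P2 to P14. All 10 tested neutrophil and marrow markers were lower at P14 (10 adjusted over the list alone; camera adjusted p = 3.36e-08, and adjusted p = 0.409 with an estimated correlation). S100a9 fell from 94.1 ± 43.0 to 1.24 ± 0.0146 FPKM and S100a8 from 94.3 ± 28.0 to 1.47 ± 0.723. Cartilage and bone markers held 8 lower and no higher genes among 14 (9 lower adjusted over the list alone; camera adjusted p = 1.18e-05, and adjusted p = 0.409 with an estimated correlation). Erythroid markers held 4 lower of 9 (6 adjusted over the list alone; camera adjusted p = 0.000127, and adjusted p = 0.409 with an estimated correlation). Adipocyte markers held 5 lower of 12 (7 adjusted over the list alone; camera adjusted p = 0.00879) and macrophage markers 3 lower of 13 (3 adjusted over the list alone; camera adjusted p = 0.0268), and for both the adjusted p = 0.409 with an estimated correlation. The call of macrophage markers was lost without P2 replicate 2 (camera adjusted p = 0.0835). Spp1, osteopontin, fell from 84.5 ± 61.2 to 0.556 ± 0.230 and Arhgap36 from 56.9 ± 11.6 to 1.27 ± 0.523. BC100530, also among the largest falls, was at 42.2 and 19.2 in the P2 libraries and was listed at 0 in both P14 libraries. Ibsp, bone sialoprotein, was at 37.3 and 9.41 in the P2 libraries and was also listed at 0 at P14. Endothelial markers held 4 higher and no lower genes among 14, the same when adjusted over the list alone (camera adjusted p = 0.000578, and adjusted p = 0.638 with an estimated correlation). Flt1 rose from 3.03 ± 0.562 to 6.14 ± 0.188 (adjusted p = 0.0859 without P14 replicate 1 and 0.0600 without P14 replicate 2). Lists not called were satellite cells with 3 lower of 13 (3 adjusted over the list alone) and fibroblasts and fibro-adipogenic cells with 3 higher and 2 lower of 13 (4 and 2 adjusted over the list alone). Also not called were mural cells with 3 higher and 1 lower of 10 (4 and 3 adjusted over the list alone) and tendon with 1 higher and 1 lower of 10, the same adjusted over the list alone. Schwann cells, not called, held none of 13 in either direction, by limma or adjusted over the list alone. Schwann cell markers were called lower without P2 replicate 1 (camera adjusted p = 0.0111) or P14 replicate 2 (0.0175), and fibroblast and fibro-adipogenic markers higher without P2 replicate 2 (0.0420). The satellite cell list had a median of 0.16 and a mean of -0.14. Skin and lymphocyte lists had 1 and 3 tested members and were not tested as lists, and no member exceeded 3.27 FPKM (skin) or 10.9 FPKM (lymphocytes) in any library.

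Camera called 20 of 30 lists at P14 versus P2 and none with an estimated correlation. That second test rests on 3 residual degrees of freedom and could call few lists, so the loss is not evidence of correlation alone. Over all 13566 tested genes, 1557 were higher and 1744 lower at P14 than at P2 by limma at an adjusted p below 0.05. Of these 866 and 767 changed by at least 1 on the log2 scale. The split depended on the scaling, with 2336 higher and 2282 lower after median-of-ratios scaling and 1402 and 4406 after scaling to the sum of protein-coding genes. The median of all genes was -0.05, and -0.29 under the latter. The counts were 343 higher and 630 lower without P14 replicate 1, 850 and 728 without P14 replicate 2, 851 and 1674 without P2 replicate 1, 2150 and 1267 without P2 replicate 2. They were 978 and 1158 without P7 replicate 1 and 982 and 1167 without P7 replicate 2. Of 91 called genes among those chosen by the naming rule, 61 stayed called in each of these 6 settings.

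From P2 to P7 most of the genes that passed the test in the values as deposited fell, among them several developmental isoforms. Rises outnumbered falls after quantile normalization (137 against 101) and median-of-ratios scaling (67 against 57). Of 13 tested developmental isoforms 6 were lower and none higher (9 lower adjusted over the list alone; camera adjusted p = 1.72e-05, and adjusted p = 0.484 with an estimated correlation). The estimated correlation of this list was -0.015, below the preset 0.01, so correlation between its genes does not account for the loss of the call. The unadjusted camera p was then 0.0161, and the fry adjusted p was 0.00281. Myl4 fell from 104 ± 11.3 to 20.3 ± 0.545 FPKM (log2 fold change -2.30 ± 0.17 SE, limma adjusted p = 0.00402), Myh3 from 88.8 ± 14.3 to 18.9 ± 0.799 (limma adjusted p = 0.0350). Myh8 fell from 1142 ± 112 to 427 ± 0.624 and Tnnt2, cardiac troponin T, from 26.9 ± 7.90 to 7.00 ± 0.0326. Other large falls were Arhgap36, from 56.9 ± 11.6 to 9.25 ± 0.0434, and Alox5ap, from 11.7 ± 5.86 to 1.44 ± 0.125. The mast cell protease genes Cpa3 and Tpsb2 fell, Cpa3 from 34.4 ± 13.1 to 7.99 ± 2.44 and Tpsb2 from 22.5 ± 4.31 to 5.12 ± 0.438. Tmem8c fell from 9.64 ± 0.188 to 3.88 ± 0.0234 (limma adjusted p = 0.0414). It was the 1 called gene among 38 of the fusion list (12 lower adjusted over the list alone; camera adjusted p = 0.00884, and adjusted p = 0.861 with an estimated correlation). Ncam1 and Cdh11, which encode adhesion molecules, were the 2 called members of the cell migration and chemotaxis list of 43 (4 lower adjusted over the list alone; camera adjusted p = 0.0473, and adjusted p = 0.873 with an estimated correlation). This list lost its call without P2 replicate 2 (0.128), P7 replicate 2 (0.186), P14 replicate 1 (0.0506) or P14 replicate 2 (0.0520). Ncam1 fell from 18.4 ± 0.257 to 7.44 ± 0.901 and Cdh11 from 15.6 ± 0.00148 to 7.96 ± 0.561. In growth signalling Igfbp2 fell from 7.49 ± 1.01 to 1.57 ± 0.545, and Igf2 was at 515 ± 98.5 and 334 ± 16.5 without passing the test. All 12 genes given here as falling lost the call without P7 replicate 1 (adjusted p from 0.0687 for Myl4 to 0.227 for Cdh11) and without P7 replicate 2 (from 0.113 for Myl4 to 0.361 for Cdh11). Without P2 replicate 1, Myh3, Myh8, Cpa3, Tmem8c, Ncam1, Cdh11 and Igfbp2 were at 0.0525. Without P2 replicate 2 these and Alox5ap were at 0.0521 (Cpa3) to 0.101 (Cdh11). Tnnt2, Alox5ap, Cpa3, Tmem8c, Ncam1, Cdh11, Igfbp2 and Myh8 were at 0.0537 to 0.0981 without P14 replicate 1 and 0.0532 to 0.0979 without P14 replicate 2.

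In the values as deposited, 15 genes rose from P2 to P7, against 137 after quantile normalization. The 4 protein-coding genes that met the naming rule were Rpl29, from 8.38 ± 0.745 to 49.6 ± 5.05 FPKM, Chic2, from 2.29 ± 0.0479 to 7.23 ± 0.849, Klf9 and Esr1. The transcription factor gene Klf9 rose from 3.78 ± 0.479 to 8.73 ± 0.398 and Esr1, the oestrogen receptor alpha gene, from 3.03 ± 0.210 to 6.40 ± 0.436. Rpl29 has processed pseudogenes, so its value is uncertain. None of 23 adult fast fibre genes passed the test over all genes (4 higher and 1 lower adjusted over the list alone). Myh4 was at 130 ± 167 and 1075 ± 70.9, Myh1 at 61.6 ± 55.5 and 322 ± 13.6 and Pvalb at 111 ± 120 and 604 ± 42.1. The list was called higher than other genes (camera adjusted p = 1.21e-12, and adjusted p = 0.818 with an estimated correlation). Of 45 cell cycle genes 4 were lower (41 adjusted over the list alone; camera adjusted p = 2.70e-12, and adjusted p = 0.818 with an estimated correlation). Mcm6, a subunit of the replicative helicase, fell from 13.7 ± 2.88 to 5.44 ± 0.578. In the imprinted growth network 2 of 18 were lower (9 adjusted over the list alone; camera adjusted p = 0.00674, and adjusted p = 0.861 with an estimated correlation). Peg10 fell from 26.5 ± 2.60 to 8.35 ± 0.435. Rpl29 lost its call without P7 replicate 2 (adjusted p = 0.0927) and Peg10 without either P7 library (0.150 and 0.277). Chic2, Klf9, Esr1 and Mcm6 lost theirs whichever library was left out, at 0.0525 without P2 replicate 1 and up to 0.113 (Mcm6) without P2 replicate 2. They were at up to 0.255 (Esr1) and 0.352 (Mcm6) without P7 replicates 1 and 2, and up to 0.0981 and 0.0974 (Esr1) without P14 replicates 1 and 2.

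Markers of blood and marrow cells were among the other lists called lower at P7 than at P2. Neutrophil and marrow markers held 1 lower of 10 (10 adjusted over the list alone; camera adjusted p = 7.54e-05, and adjusted p = 0.818 with an estimated correlation), with a median of -1.19. This call was lost without P2 replicate 1 (0.0551). Erythroid markers held 3 lower of 9 (5 adjusted over the list alone; camera adjusted p = 0.00400, and adjusted p = 0.818 with an estimated correlation), and macrophage markers none of 13 (7 lower adjusted over the list alone; camera adjusted p = 0.00656, and adjusted p = 0.818 with an estimated correlation). Of 47 replication-dependent histones 2 were lower (38 adjusted over the list alone; camera adjusted p = 3.35e-09, and adjusted p = 0.842 with an estimated correlation). The extracellular matrix list held 2 lower of 45 (13 adjusted over the list alone; camera adjusted p = 0.00170, and adjusted p = 0.873 with an estimated correlation). Ribosomal proteins held 1 lower of 63 (1 adjusted over the list alone; camera adjusted p = 0.00158, and adjusted p = 0.873 with an estimated correlation). Their calls were lost without P2 replicate 2 for the extracellular matrix (0.0940) and without P7 replicate 1 for ribosomal proteins (0.123).

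Other lists were called higher than other genes at P7 with no called member. Excitation-contraction coupling had a median of 0.33 (none of 30 adjusted over the list alone; camera adjusted p = 9.75e-14, and adjusted p = 0.818 with an estimated correlation). Oxidative phosphorylation had a median of 0.06 (none of 55 adjusted over the list alone; camera adjusted p = 3.35e-09, and adjusted p = 0.861 with an estimated correlation). The circadian clock list had a median of 0.08 (none of 17 adjusted over the list alone; camera adjusted p = 0.00331, and adjusted p = 0.818 with an estimated correlation). Glycolysis and glycogen had a median of 0.0027 (1 lower of 33 adjusted over the list alone; camera adjusted p = 0.00135, and adjusted p = 0.861 with an estimated correlation). That call was lost without P2 replicate 1 (0.116). Endothelial markers had a median of 0.04 (none of 14 adjusted over the list alone; camera adjusted p = 0.00290, and adjusted p = 0.861 with an estimated correlation). The median of endothelial markers was -0.29 without P2 replicate 1 and -0.01 without P7 replicate 1, and both times the call was lost (0.875 and 0.0515).

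In total 15 genes were higher and 160 lower at P7 than at P2, camera called 17 of 30 lists and none with an estimated correlation, and 3729 had an unadjusted p below 0.05. The median of all tested genes was -0.27 on the log2 scale. The split depended on the scaling, with 67 higher and 57 lower after median-of-ratios scaling, 137 and 101 after quantile normalization and 57 and 118 after scaling to the sum of protein-coding genes. Of the 175 calls in the values as deposited, 70 remained after median-of-ratios scaling. Among genes chosen by the naming rule, 13 then lost the call and 4 gained one. After quantile normalization 9 lost it and 10 gained one. Counts were 6 higher and 12 lower without P7 replicate 1, 5 and 6 without P7 replicate 2, 15 and 36 without P2 replicate 1, 28 and 43 without P2 replicate 2. They were 12 and 26 without P14 replicate 1 and 12 and 27 without P14 replicate 2. None of the 26 called genes among those chosen by the naming rule stayed called in all 6 settings.

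From P7 to P14 many metabolic and contraction genes rose, and Myh8 and Myh3 fell. Slc25a25, a mitochondrial carrier, rose from 3.15 ± 0.471 to 42.2 ± 12.4 FPKM (log2 fold change 3.35 ± 0.23 SE, limma adjusted p = 0.00305). Fbxo40 rose from 4.38 ± 0.595 to 41.0 ± 6.60, Ankrd9 from 1.75 ± 0.440 to 18.2 ± 3.26, Klhl33 from 2.58 ± 0.177 to 22.9 ± 3.30 and Lrrc30 from 2.13 ± 0.0496 to 17.5 ± 4.86. Actc1, cardiac alpha-actin, rose from 189 ± 38.1 to 1193 ± 567, and its sequence is close to that of other actin genes, so that the value is uncertain. Its adjusted p was 0.140 without P7 replicate 1, 0.113 without P7 replicate 2 and 0.0973 without P14 replicate 1. Fatty acid oxidation held 20 higher and no lower genes among 28 (26 higher adjusted over the list alone; camera adjusted p = 7.29e-10, and adjusted p = 0.508 with an estimated correlation). Glycolysis and glycogen held 21 higher of 33 (29 adjusted over the list alone; camera adjusted p = 1.91e-09, and adjusted p = 0.591 with an estimated correlation). Oxidative phosphorylation held 33 higher of 55 (55 adjusted over the list alone; camera adjusted p = 6.65e-14, and adjusted p = 0.615 with an estimated correlation). Excitation-contraction coupling held 18 higher and 1 lower of 30 (25 and 1 adjusted over the list alone; camera adjusted p = 2.96e-07, and adjusted p = 0.626 with an estimated correlation). Acadvl, an acyl-CoA dehydrogenase, rose from 23.3 ± 2.44 to 78.8 ± 15.6, Phka1 from 9.32 ± 0.419 to 53.0 ± 17.2 and S100a1 from 6.06 ± 0.436 to 31.8 ± 5.08. Of adult fast fibre genes 9 of 23 were higher and none lower (19 higher adjusted over the list alone; camera adjusted p = 5.94e-06, and adjusted p = 0.626 with an estimated correlation). Mylk2 rose from 15.04 ± 1.57 to 51.9 ± 4.41, while Myh4, at 1075 ± 70.9 and 2601 ± 565, did not pass the test. Slc25a25, Fbxo40, Ankrd9, Klhl33 and Myh8 stayed called without each of the 6 libraries in turn. Without P7 replicate 1, P7 replicate 2 and P14 replicate 1, in that order, the adjusted p was 0.121, 0.111 and 0.0973 for Lrrc30, 0.110, 0.106 and 0.0770 for Mylk2, 0.105, 0.0891 and 0.0582 for S100a1, and 0.110, 0.0993 and 0.0582 for Phka1. For Acadvl it was 0.138, 0.154 and 0.124, and 0.0564 without P14 replicate 2. The circadian clock list held 5 higher of 17 (10 adjusted over the list alone; camera adjusted p = 0.00613, and adjusted p = 0.508 with an estimated correlation). Endothelial markers held 2 higher of 14 (4 adjusted over the list alone; camera adjusted p = 0.0291, and adjusted p = 0.867 with an estimated correlation), a call lost without P7 replicate 2 (0.111) or P14 replicate 2 (0.0715).

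Falls from P7 to P14 were fewer than rises in the values as deposited, 217 against 1187, but outnumbered them after scaling to the sum of protein-coding genes, 1403 against 570. Of 13 developmental isoforms 4 were lower and 1, Actc1, was higher (6 and 2 adjusted over the list alone; camera adjusted p = 7.13e-05, and adjusted p = 0.458 with an estimated correlation). Myh8 fell from 427 ± 0.624 to 30.8 ± 3.08 FPKM (limma adjusted p = 0.00201), Myh3 from 18.9 ± 0.799 to 4.86 ± 2.33 (limma adjusted p = 0.0237). Sln fell from 86.2 ± 13.3 to 7.81 ± 3.35 (limma adjusted p = 0.00984). The imprinted growth network held 10 lower and no higher genes among 18 (11 lower and 1 higher adjusted over the list alone; camera adjusted p = 6.65e-14, and adjusted p = 0.458 with an estimated correlation). Dlk1 fell from 88.4 ± 5.39 to 20.8 ± 1.43, and Igf2 fell from 334 ± 16.5 to 170 ± 9.52 (limma adjusted p = 0.0466). Of 45 cell cycle genes 12 were lower (22 adjusted over the list alone; camera adjusted p = 1.21e-24, and adjusted p = 0.458 with an estimated correlation). Of 14 cartilage and bone markers 6 were lower (10 adjusted over the list alone; camera adjusted p = 1.34e-13, and adjusted p = 0.458 with an estimated correlation). Col2a1, cartilage collagen, fell from 27.2 ± 1.88 to 3.02 ± 0.443. Spp1 fell from 27.1 ± 14.4 to 0.556 ± 0.230 and S100a9 from 23.7 ± 14.0 to 1.24 ± 0.0146. Without P7 replicate 1, P7 replicate 2 and P14 replicate 1, in that order, the adjusted p was 0.156, 0.154 and 0.120 for Myh3 and 0.0886, 0.0881 and 0.0582 for Sln. Without these and P14 replicate 2 it was 0.112, 0.0891, 0.0757 and 0.0522 for Dlk1, 0.213, 0.220, 0.227 and 0.150 for Igf2, 0.180, 0.181, 0.172 and 0.0909 for Col2a1, and 0.126, 0.0881, 0.118 and 0.0623 for Spp1. S100a9 was at 0.111 without P7 replicate 1, 0.109 without P14 replicate 1 and 0.0637 without P14 replicate 2. Replication-dependent histones held 13 lower of 47 (31 adjusted over the list alone; camera adjusted p = 1.84e-29, and adjusted p = 0.458 with an estimated correlation), and neutrophil and marrow markers 4 of 10 (6 adjusted over the list alone; camera adjusted p = 6.65e-11, and adjusted p = 0.458 with an estimated correlation). Erythroid markers held 2 lower of 9 (3 adjusted over the list alone; camera adjusted p = 0.000107, and adjusted p = 0.508 with an estimated correlation). Adipocyte markers held 1 lower of 12 (1 adjusted over the list alone; camera adjusted p = 0.0174, and adjusted p = 0.508 with an estimated correlation), a call lost without P14 replicate 1 (0.271). Ribosomal proteins were called higher than other genes with a median of 0.48 but 1 higher of 63 (none adjusted over the list alone; camera adjusted p = 0.0174, and adjusted p = 0.867 with an estimated correlation). The median of ribosomal proteins was -0.17 under quantile normalization, and the call was lost without P7 replicate 1 (0.249) or P14 replicate 1 (0.298). The extracellular matrix list had a median of 0.17 and a mean of 0.08 but was called lower than other genes, with 2 lower of 45 (2 adjusted over the list alone; camera adjusted p = 0.0433, and adjusted p = 0.867 with an estimated correlation). That call was lost without P2 replicate 1 (0.150), P2 replicate 2 (0.147), P7 replicate 1 (0.0603), P7 replicate 2 (0.0507) or P14 replicate 2 (0.114). The median of all genes was 0.23. Immediate early and stress genes held 6 higher of 17, the same adjusted over the list alone (camera adjusted p = 0.00612, and adjusted p = 0.4997 with an estimated correlation). The immediate early and stress list lost its call without P14 replicate 2 (0.0809). Nr4a1 rose from 2.34 ± 0.352 to 16.0 ± 3.27 (adjusted p = 0.0680 without P7 replicate 1).

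In total 1187 genes were higher and 217 lower at P14 than at P7, and camera called 18 of 30 lists and none with an estimated correlation. The split depended on the scaling, with 980 higher and 781 lower after median-of-ratios scaling, 640 and 552 after quantile normalization and 570 and 1403 after scaling to the sum of protein-coding genes. Fewer genes were called when any P7 or P14 library was left out. A stage then holds 1 library, which is itself a cause of fewer calls. In these settings the log2 change of Sln lay between -2.95 and -3.75, against -3.35 with both libraries of P7 and P14. That of Spp1 lay between -3.53 and -4.63, against -4.08. The counts were 2485 and 417 without P2 replicate 1 and 2493 and 417 without P2 replicate 2. Of 70 called genes among those chosen by the naming rule, 5 stayed called in all 6 of these settings.

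**Figure D3:**
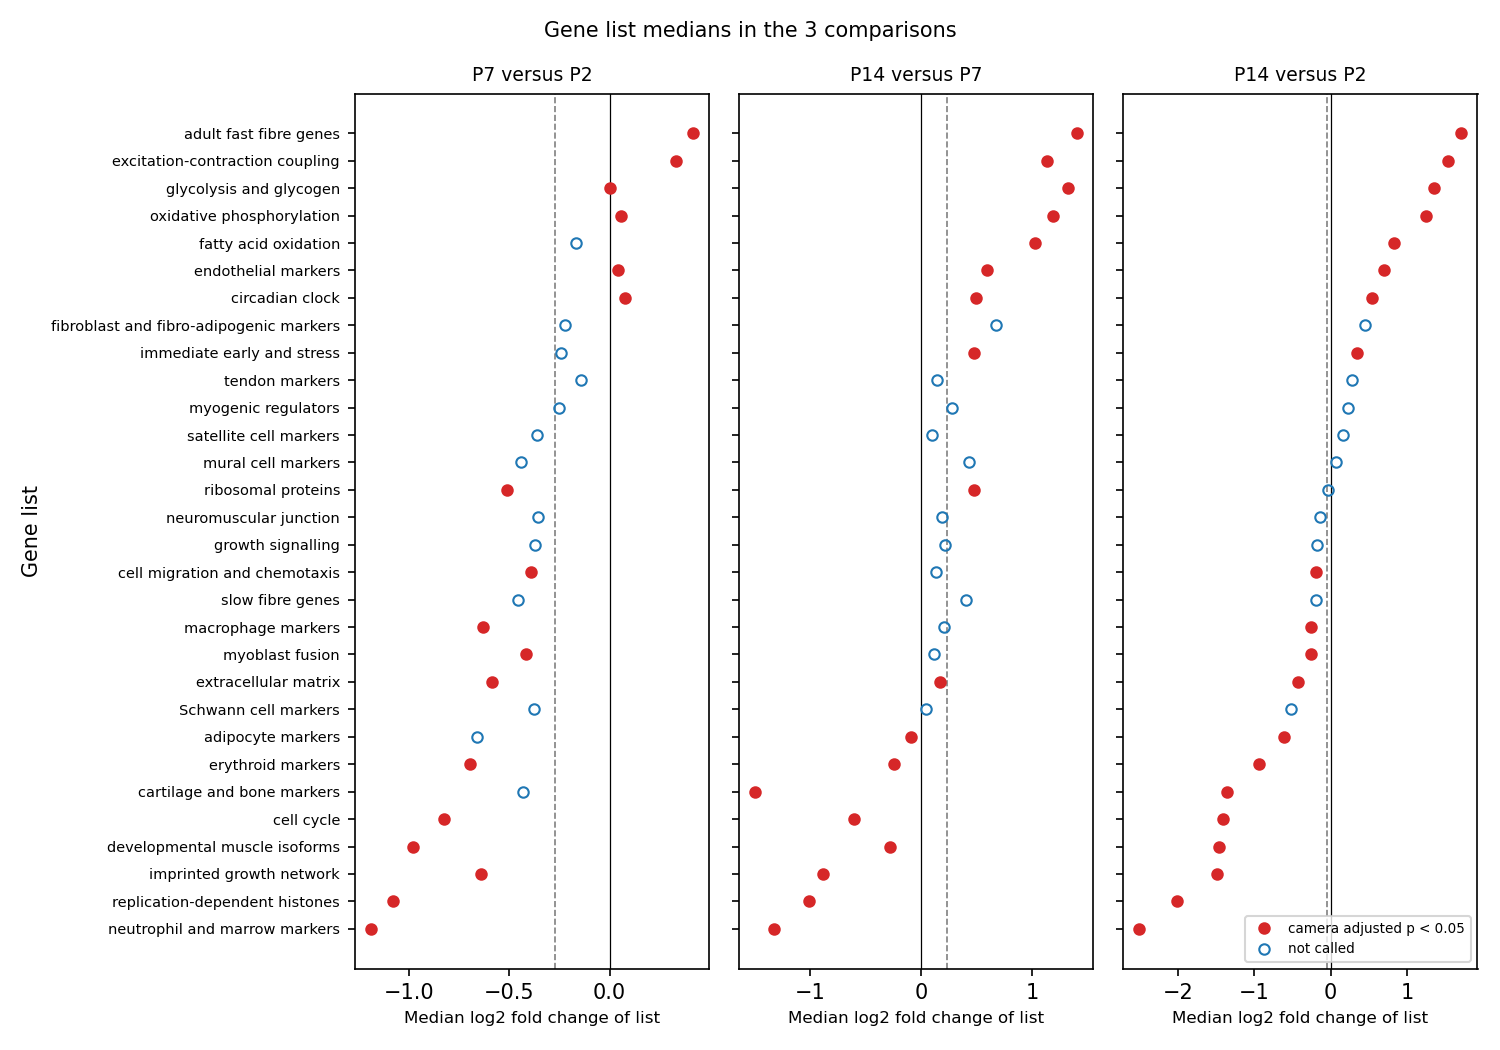
Median log2 fold change of each of 30 gene lists (x axis) in the 3 comparisons. Filled points are lists called by camera with its preset correlation, open points the others, the solid line 0 and the dashed line the median of all tested genes. No list was called with an estimated correlation, a test on 3 residual degrees of freedom that could call few lists. The ribosomal protein median of 0.48 in P14 versus P7 was -0.17 under quantile normalization. The endothelial median of 0.04 in P7 versus P2 was -0.29 without P2 replicate 1.

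Across the 3 stages 2861 of 13566 genes differed by the F test of limma. Between 422 and 861 genes did so in the 4 settings without a P7 or P14 library. Genes called in opposite directions in the 2 steps were rare, with 6 that peaked at P7 and 5 with a trough there. With protein-coding genes only there were 5 peaks and 29 troughs, and with no filter 4 and 0. The 2 steps share the P7 libraries. Simulated unchanged stages gave a mean of 0 peaks and 0.05 troughs over 20 simulations, and independent lists of the observed lengths would share 0.240 peaks and 14.0 troughs. The simulation drew independent normal values for each gene, with no floor at 0 and no shift shared by the genes of a library. It therefore gives no chance value for genes listed at 0 in most libraries, or for troughs under the lower median at P7. The 2 protein-coding trough genes that met the naming rule were Osbpl5, at 8.33 ± 1.52, 3.45 ± 0.342 and 7.23 ± 0.186 FPKM at P2, P7 and P14, and Amotl2, at 11.5 ± 0.365, 5.56 ± 0.0166 and 9.62 ± 1.27. Neither stayed a trough whichever library was left out. The fall lost its call in all 6 settings, at adjusted p of 0.0525 for both without P2 replicate 1, and for Osbpl5 and Amotl2 in turn 0.102 and 0.113 without P2 replicate 2, 0.223 and 0.249 without P7 replicate 1, and 0.352 and 0.356 without P7 replicate 2. It was 0.0892 and 0.0886 without P14 replicate 1, and 0.0889 and 0.0879 without P14 replicate 2. All 6 peak genes were short non-coding RNAs or pseudogenes listed at 0 in the P2 and P14 libraries, the most abundant being mmu-mir-668 at 248 and 114 in the P7 libraries. This gene was chosen for mention after its values were seen.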

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

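The added alternatives, a sex term and the adjustment of the authors' p-values, were chosen after seeing the data. Over all settings 5197 values for named genes stayed on the same side of the threshold, 762 lost the call and 197 gained one. With a call in either setting, 0 reversed direction. For lists these were 1699, 146, 34 and 5, by the direction of the test. A change of direction between values that were both not called was counted as staying the same. With 2 libraries per stage, leaving out a library leaves a lone library that is assumed to vary like the others, and fewer libraries are themselves a cause of fewer calls; the other causes were not tested. Counts below are given as higher and lower.

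P7 versus P2 gave 7 and 22 with a pseudocount of 0.1, a lower count of 262 with a pseudocount of 5, 5 and 8 with no filter, 67 and 57 with median-of-ratios scaling, 137 and 101 with quantile normalization, a higher count of 57 with protein-coding sum scaling, 37 and 657 with protein-coding genes only, 28 and 287 with robust eBayes, 7 and 30 with a sex term, a lower count of 25 with only the 4 libraries compared, and a higher count of 214 with the authors' p adjusted here. P14 versus P7 gave 2 and 5 with no filter, a lower count of 781 with median-of-ratios scaling, 640 and 552 with quantile normalization, 570 and 1403 with protein-coding sum scaling, 1981 and 328 with protein-coding genes only, a lower count of 130 with a sex term, 2466 and 410 with only the 4 libraries, 653 and 122 with a log2 change of at least 1, and a lower count of 762 with the authors' p. P14 versus P2 gave 619 and 915 with no filter, a lower count of 886 with an FPKM filter of 5, a higher count of 2336 with median-of-ratios scaling, a lower count of 4406 with protein-coding sum scaling and 1153 with a sex term, a higher count of 988 with only the 4 libraries, and 866 and 767 with a log2 change of at least 1.

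Genes differing among the 3 stages numbered 401 with no filter, 4581 with protein-coding sum scaling and 1820 with a sex term. Peaks numbered 3 with a pseudocount of 0.1, 2 with an FPKM filter of 5 and 10 with quantile normalization. Troughs numbered 3 with a pseudocount of 0.1 or 5, with quantile normalization and with no variance trend, 0 with no filter, 2 with median-of-ratios and with protein-coding sum scaling, 29 with protein-coding genes only, 9 with robust eBayes and 1 with a sex term. Leaving out a library gave 5 to 28 and 6 to 43 for P7 versus P2, 7 to 2493 and 7 to 417 for P14 versus P7, 343 to 2150 and 630 to 1674 for P14 versus P2, 422 to 3954 over the 3 stages, and 0 to 4 troughs. No list was called with an estimated correlation (0, 0 and 0), a test on 3 residual degrees of freedom that could call few lists. The test fry called 1 in P7 versus P2, 5 in P14 versus P7 and 15 in P14 versus P2. It asks whether a list changed at all, not whether it changed more than other genes as camera does. Developmental muscle isoforms were called by fry in each comparison, at adjusted p of 0.00281, 0.0285 and 0.00142 in that order. The direction of the test turned, at an unchanged median, for the extracellular matrix list (P14 versus P7, 0.17, with no filter and with fry) and glycolysis (P7 versus P2, 0.0027, with fry). The median of all genes was 0.230 in P14 versus P7 and -0.271 in P7 versus P2. With fry the question differs, so that turn does not show that the lists changed otherwise. The median itself changed sign for ribosomal proteins (P14 versus P7, -0.17 with quantile normalization) and endothelial markers (P7 versus P2, -0.29 without P2 replicate 1 and -0.01 without P7 replicate 1), which were at 0.36 without P2 replicate 2, in the direction seen with all libraries.

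The stages share the replicate numbers of the sample titles, which do not all match the numbers in the submitters' library names. Deviations of libraries with the same title number correlated at -0.019, -0.159 and 0.030. Each value rests on 1 difference per stage, so it shows no pairing by title number but cannot exclude it. Pairing by the submitters' own numbers was not tested. A replicate block gave 8 and 27 for P7 versus P2, 224 and 77 for P14 versus P7, 1463 genes over the 3 stages and 1 trough. The planned use of the authors' adjusted calls was not run as written, since the tables used here hold unadjusted p-values.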

Other observations

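The tests of explanations in this part were chosen after the results were seen, and so were the non-coding genes named here other than Mirg, a member of the imprinted growth network list. Of 635 tested long non-coding RNAs, 74 were higher and 66 lower at P14 than at P2 in the planned limma comparison, though the class was picked out afterwards. Nctc1, on chromosome 7, rose from 0.306 and 0.967 FPKM in the P2 libraries through 10.2 and 12.3 at P7 to 61.1 and 61.6 at P14. Gm12300, annotated antisense on chromosome 11 (67211255 to 67237573), rose from 3.68 and 22.6 to 177 and 153. It overlaps Myh1 (67200051 to 67224575) and ends before Myh4, and since strand use in counting is not given, fragments of Myh1 are not excluded from its value. Mirg, B830012L14Rik, Gm26945 and Gm26906, all on chromosome 12, fell between P2 and P14: Mirg from 134 ± 19.4 to 29.4 ± 2.38, B830012L14Rik from 21.3 ± 0.608 to 3.03 ± 0.0804, Gm26945 from 52.7 ± 4.68 to 8.94 ± 0.976 and Gm26906 from 82.3 ± 10.8 to 17.8 ± 1.61. Nespos, antisense on chromosome 2, fell from 33.7 ± 0.796 to 5.31 ± 0.452. Summed mitochondrially encoded mRNAs were at 14495 and 15260 FPKM at P2, 16481 and 22929 at P7 and 29495 and 28362 at P14.

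Most genes had a lower FPKM in the P7 libraries, with a median P7 minus P2 of -0.271. The mean FPKM of 1086 olfactory receptor genes, taken as background, was inversely ordered to the median-of-ratios factor over 6 libraries (rho -0.943, exact p = 0.0167, adjusted 0.0167; r -0.947, exact p = 0.00694, adjusted 0.0139; r -0.942 over 4 libraries without P7 replicate 1 and P14 replicate 1; 2 relations tested), and within 3 of 3 stages, consistent with background reads taking a varying share. Both quantities share the library scaling, so the test cannot tell cause from consequence. The share of the 10 most abundant transcripts would shift other genes by -0.052 from P2 to P7, against the median of -0.271, and by 0.0766 from P7 to P14, against 0.230, so that it gives only a part in both and a contribution stays open. The shift from P7 to P14 came from P14 replicate 1, where this share of exonic fragments was 13.3%. It was 21.2% in P14 replicate 2 and 21.5% and 21.6% in the P7 libraries. Stage itself was not tested as a biological explanation.

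The P2 libraries differed in many lists, with replicate 2 minus replicate 1 at a median of 0.675 for adult fast fibre genes (21 of 23 above the median gap of all genes, 0.246), 1.08 for Schwann cell, 0.773 for endothelial and 0.686 for fibroblast markers and 0.613 for extracellular matrix, but -0.829 for cartilage and bone and -0.552 for neutrophil and marrow markers. For the fast fibre genes, a sex effect acting alike at P2 and P7 is argued against by the P7 libraries, where the Xist-expressing library differed by 0.018 in the same list. A larger muscle share with a smaller share of every other tissue is not supported in that form. Endothelial markers lay 0.527 above all genes (SD 0.302) and 1.51 above cartilage, bone and marrow markers (SD 0.687). A test of fast fibre genes against developmental isoforms (0.659 apart, SD 0.949 and 0.436) did not decide on a larger muscle share. A carried-along share of cartilage, bone and marrow that differed between the P2 libraries was not tested and stays open. A sex effect at P2 alone stays open, because sex cannot be separated from the 2 P2 libraries. A more mature replicate 2 also stays open, because the developmental isoforms lay -0.230 from all genes with an SD of 0.436.

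Cartilage, bone and marrow markers were lower at P14. Endothelial markers had a median change of 0.696, so the fall did not extend to the markers of every other cell type. They changed by 2.52 more than these markers (permutation p = 2e-05, near the smallest that 100000 permutations give). These sets were compared after endothelial markers were called higher and the others lower, so a large difference was fixed beforehand. The comparison cannot decide on a smaller share of cartilage, bone and marrow alone. The permutations here and below shuffled genes, so their p-values do not measure the spread between samples, of which each stage had 2. Genes of a list were not independent (estimated correlation 0.92 for endothelial, 0.74 for neutrophil and marrow and 0.52 for cartilage and bone markers). A single carried-along tissue of fixed composition is not supported. From P2 to P7 the 7 cartilage genes exceeded the 14 bone or marrow genes by 2.05 (permutation p = 0.00156). The mean log2 difference of these sets was -1.435 and -1.94 in the P2 libraries and -0.223 and 0.892 in the P7 libraries. Cartilage genes alone had mean log2 values of 2.73 and 1.49 at P2 and 2.70 and 2.79 at P7, so their rise came from P2 replicate 2. Changes in these tissues with stage remain a biological explanation that was not tested. A carried-along share that varied between samples was not tested either.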
